A study of Mus musculus with 9 samples.

How the data were processed

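Gene expression was measured in cultured mouse cells of 3 knockout lines, EBFko, Pax5ko and RAG2ko, with 3 samples per line and 1 Affymetrix expression array per sample. The labels report total RNA, an integrity check of the RNA on a bioanalyzer, and biotin labelling by in vitro transcription.

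The deposited matrix holds 1 signal intensity per probe set and array, on a linear scale, for 45101 probe sets and 9 arrays. The labels name GCRMA as the processing tool. The values carry a different mark: the mean after trimming 2% at each end was 500.003 or 500.004 on every array, and the arrays did not share a common distribution. The step that made these values is not stated, and the plan written before the data were examined described them as log2 GCRMA values, which they were not. The deposited table of each knockout holds 1 ratio per probe set, on a linear scale, relative to a reference that is not stated and without replicates; these tables were matched to the lines by name and used only as an alternative source of values.

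Signals were log2 transformed and quantile normalized over the 9 arrays. Control probe sets (64) were left out. The arrays' annotation was not used beyond the accession and description in the tables: 13127 probe sets were named by a RefSeq accession that led to 1 symbol, 4965 by a description shared with such a probe set and 162 by 1 of 72 full gene names matched by hand. This gave 18254 probe sets with 1 symbol for 9959 genes, and left 26842 without. Genome coordinates were not used here. Probe sets needed a log2 signal above 4 on at least 3 of the 9 arrays, and each gene was represented by its probe set with the highest mean, which left 9375 genes.

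The 3 comparisons were fitted together on all 9 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes tested and calls at an adjusted p under 0.05. The 24 gene lists, fixed before the data were examined, covered B cell receptor components, B lineage transcription factors, genes activated and repressed by Pax5, V(D)J recombination, mature B cells, T, NK, myeloid, dendritic, stem, erythroid, mast and stromal cells, Notch, IL-7 and Flt3 signalling, chemokine receptors, cell cycle, D cyclins, apoptosis, glycolysis, interferon response, plasma cells and stress genes. They were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 24 lists of a comparison. For some lists the estimate lay below the preset value, such as 0.00098 for NK genes and -0.044 for dendritic genes. A shift lost in such a list does not come from correlation between its members, so the settings differ in more than the correlation. Member counts adjusted over the list alone are given beside those over all genes. Genes in a pattern over the 3 lines passed both comparisons concerned.

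Named genes followed a rule written before the data were examined. It took 18 genes fixed in advance, 1 of which is not reported here, the 10 largest rises and the 10 largest falls of each comparison among called genes whose groups did not overlap, and up to 2 rises and 2 falls per list. Unnamed, predicted and Y-linked genes and Xist were left out of the rule. Members given for a pattern over the 3 lines were chosen after their values were seen, as was Pdgfrb.

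On simulated data of 9375 genes with 100 changed genes per size, the pipeline recovered 28%, 26% and 40% of changes of 1 on the log2 scale and 65%, 58% and 46% of changes of 2 in Pax5ko minus EBFko, RAG2ko minus Pax5ko and RAG2ko minus EBFko, without a wrong sign. Each comparison was simulated with the same spreads, so these rates differ between comparisons only by the random draw. A list with a simulated shift passed camera and a list without one did not. All genes of the shifted list were raised and the simulated genes were independent, so this did not check the preset correlation. False calls made up 6.06%, 7.69% and 11.3% of the calls. No array was a copy of another.

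Alternatives changed 1 choice at a time: no quantile normalization, centring on each array's median, no filter or a filter at 6, probe sets of a gene averaged, no probe sets marked as matching several transcripts, eBayes with trend and robust settings, array weights, replicate number as a block, a fit on the 6 arrays compared, calls of at least 2-fold, the ratio tables, and each array left out in turn. Raising signals below 64 to 64, a filter at 8 and a test of every probe set were added after seeing the data. All splits of the 6 arrays of a comparison, 10 per comparison, were also tested.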

Results

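RNA from cultured mouse cells of 3 knockout lines was measured on Affymetrix expression arrays of 45101 probe sets, with 3 arrays per line. The labels name the lines as deficient in EBF (EBFko), Pax5 (Pax5ko) or RAG2 (RAG2ko) and describe them as lymphoid specified, B lineage specified and B lineage committed. EBF1 and PAX5 are transcription factors of the B lineage, and RAG2 is a subunit of the recombinase that assembles antigen receptor genes. EBFko and Pax5ko cells grew with 10 ng/ml Flt3 ligand and 10 ng/ml IL-7, while RAG2ko cells grew with 10 ng/ml IL-7 alone, so the medium changed together with the genotype in both comparisons with RAG2ko. Sex-linked transcripts also differed between the lines, Pax5ko and EBFko included, so no comparison can be read as one of genotype alone. The median signal of an array lay between 73.4 and 97.6, and 41.0% to 47.3% of its probe sets had a signal below 64, which is 6 on the log2 scale. Without detection calls, such dim signals could not be separated from background. Tests covered 9375 genes, and the number of arrays limited their precision. The labels do not say whether the 3 samples of a line were separate cultures, so the p-values measure only the spread between these samples. Group levels below are mean log2 signals ± SD of 3 arrays, and differences are log2 differences ± SE from the limma fit. The fit shares the spread of a gene over the 3 lines, so scatter in the line not compared can keep a gene from passing. For single genes in the fit of all arrays, where a group mean lay below 6, the size of a difference rests on dim signal, and the difference after raising signals below 64 to 64 follows as its floor. This floor is not a lower limit, and the deposited ratios gave smaller differences for some genes. Genes picked for the size of their change were ranked without that floor.

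Arrays of a line resembled each other more than arrays of other lines. Across the genes tested, which are not independent replicates, the correlation between arrays ranged from 0.937 to 0.949 within EBFko, 0.942 to 0.951 within Pax5ko and 0.919 to 0.936 within RAG2ko. Between lines it ranged from 0.896 to 0.909 for EBFko with Pax5ko, 0.858 to 0.895 for Pax5ko with RAG2ko and 0.840 to 0.879 for EBFko with RAG2ko. Ebf1 was represented by 3 probe sets, all bright on arrays labelled EBFko, the dimmest of them at 9.53. The probe set tested was bright on those arrays (10.87 ± 0.21), on those labelled Pax5ko (9.98 ± 0.09) and on those labelled RAG2ko (12.01 ± 0.37). The structure of the knockout alleles and the position of the probes are not given in the sources used here, so these signals check no genotype. Ebf1 was lower in Pax5ko than in EBFko by 0.89 ± 0.21 (adjusted p = 0.0349), a call that several alternatives lost. The Pax5 probe set gave 5.14 ± 1.80 in EBFko, 3.94 ± 1.52 in Pax5ko and 7.10 ± 0.30 in RAG2ko, and no comparison passed the test. Rag2 gave 9.39 ± 0.69, 7.55 ± 0.35 and 6.89 ± 1.92 in the same order and also passed in no comparison. Its signal was 5.96 and 5.60 on RAG2ko replicates 1 and 2 but 9.10 on replicate 3, and without replicate 3 Rag2 passed the test in all 3 comparisons, at -3.60 for RAG2ko minus EBFko, a size that rests on the dim signals of the 2 remaining RAG2ko arrays.

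Transcripts of stromal cells, a cell type used as feeder layer for lymphoid cultures, were also measured with a list of 20 genes, 19 of them tested; the labels name no feeder layer. Their mean log2 signal was 9.13 ± 0.84 in EBFko, 9.26 ± 0.94 in Pax5ko and 7.23 ± 1.61 in RAG2ko. Within RAG2ko it was 5.96 and 6.68 on replicates 1 and 2 and 9.04 on replicate 3. In the other lines, replicate 2 had the lowest mean, 8.18 in EBFko and 8.22 in Pax5ko. Replicate 3 had the highest mean in all 3 lines, 9.75 in EBFko and 10.05 in Pax5ko.

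Pax5ko against EBFko asks what sets cells described as B lineage specified apart from those described as lymphoid specified. Several genes of the pre-B cell receptor were far higher in Pax5ko. Vpreb1, part of the surrogate light chain, rose by 10.43 ± 0.89 (floor 8.11), from 3.70 ± 2.07 in EBFko to 14.13 ± 0.14 in Pax5ko (adjusted p = 6.17e-04). Igll1, its partner in that chain, rose by 6.73 ± 0.14 (adjusted p = 8.90e-07), Vpreb2, whose only probe set is marked as matching several transcripts, by 7.35 ± 0.12 (floor 7.09) and Cd79a, a signalling chain of the B cell receptor, by 4.32 ± 0.26 (floor 3.58, adjusted p = 1.43e-04). Pou2af1, a coactivator of transcription in B cells, rose by 8.97 ± 0.32 (floor 6.96), and Dntt, which adds nucleotides at V(D)J junctions, by 3.82 ± 0.49. The deposited ratios, which have no replicates, gave 6.56 for Vpreb1, 6.64 for Vpreb2 and 6.63 for Pou2af1, below these floors. Igll1 and Erg gave nearly the same values, 6.64 and 6.63, although their differences in the fit were unlike. The ratios may therefore not measure the size of each of these differences. For Cd79a the ratio was 4.54, above its floor.

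Not all B cell genes moved that way. Blnk, the adaptor that links the receptor to its downstream enzymes, fell by 3.80 ± 0.49 (floor 2.97) in Pax5ko (adjusted p = 0.00334), and Cd72 fell by 4.98 ± 0.41 (floor 4.45). Igll1 lost its call when probe sets marked as matching several transcripts were left out.

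Several genes of progenitors and of other lymphoid lineages were lower in Pax5ko. As whole lists, the T cell and the NK genes lost their shift with an estimated correlation (adjusted p = 0.0718 and 0.0718), and the progenitor genes did not pass. In the progenitor list 4 members rose and 8 fell, with Erg (8.37 ± 0.32, floor 4.63) and Lmo2 (1.15 ± 0.21) among the rises. Cd34, a surface protein of blood progenitors, fell by 9.30 ± 0.67 (floor 6.63, adjusted p = 2.99e-04), and Hoxa7 by 5.81 ± 0.28 (floor 4.22). Cd7, a marker of early T and NK cells, fell by 6.29 ± 0.15 (floor 4.16). Klrd1, an NK receptor chain, fell by 8.59 ± 1.26 (floor 4.52) and Il18r1 by 7.84 ± 1.37 (floor 5.33). Id2, an inhibitor of E proteins needed by NK cells, fell by 3.49 ± 0.29 (adjusted p = 5.55e-04), and the cytokine receptor Flt3 by 2.18 ± 0.29. The receptor Notch1 rose by 1.23 ± 0.24 (adjusted p = 0.0173), a call that was lost without EBFko replicate 1 or 3. The difference was -1.21 for Kit, -2.69 (floor -0.55) for Gata3, -1.85 (floor -1.10) for Tcf7, 1.67 for Rag1, -0.22 for Il7r and 0.58 for Csf1r, and none of these passed.

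Rises picked for their size outside the B cell lists included Tmed6 (9.56 ± 0.39, floor 5.55), Crisp1 (9.48 ± 0.48, floor 7.10), ccdc198 (9.68 ± 0.47, floor 7.47) and the growth factor Igf2 (9.31 ± 0.67, floor 8.15). Fgf13 rose by 9.14 ± 0.25 (floor 4.50), the transcription factor Erg by 8.37 ± 0.32 (floor 4.63) and Plagl1 by 8.10 ± 1.24 (floor 5.79). The Plagl1 call was lost when probe sets marked as matching several transcripts were left out. Falls picked for their size included Tnni1 (8.91 ± 0.57, floor 6.31), Cdh17 (7.31 ± 0.82, floor 4.04), P2ry14 (6.94 ± 0.71, floor 4.93), Espn (6.17 ± 0.48, floor 2.66) and Syce2 (6.06 ± 0.19, floor 5.70).

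Of the 24 gene lists, 5 shifted in this comparison by limma's camera test, and none did with an estimated correlation. In the pre-B and B cell receptor list, 10 of 23 tested members rose and 6 fell (10 and 7 adjusted over the list alone), with a median difference of 0.31 (adjusted p = 0.00935, and adjusted p = 0.504 with an estimated correlation). This shift was lost without the probe sets marked as matching several transcripts. The T cell list was lower: 0 of 21 tested members rose and 6 fell (1 and 12 adjusted over the list alone), with a median of -1.03 (adjusted p = 2.12e-04, and adjusted p = 0.0718 with an estimated correlation). In the NK and innate lymphoid list, 0 of 25 tested members rose and 8 fell (0 and 10 adjusted over the list alone), with a median of -1.17 (adjusted p = 0.00179, and adjusted p = 0.0718 with an estimated correlation). In the dendritic list, 1 of 13 tested members rose and 6 fell (1 and 7 adjusted over the list alone), with a median of -1.35 (adjusted p = 0.00620, and adjusted p = 0.106 with an estimated correlation), and Cox6a2 fell by 3.92 ± 0.26. Of the chemokine receptor and adhesion genes, 2 of 19 tested members rose and 7 fell (2 and 8 adjusted over the list alone) (adjusted p = 0.00303, and adjusted p = 0.109 with an estimated correlation), among them Itgb7, which fell by 3.54 ± 0.26, while Cxcr3 rose by 2.54 ± 0.31. Neither Pax5 list shifted: of genes known to be activated by Pax5, 4 of 17 tested members rose and 4 fell (4 and 5 adjusted over the list alone) (adjusted p = 0.919), and of those known to be repressed by it, 3 of 17 tested members rose and 4 fell (3 and 4 adjusted over the list alone) (adjusted p = 0.809). The stem and multipotent progenitor list, in which 4 of 24 tested members rose and 8 fell (5 and 10 adjusted over the list alone), did not pass (adjusted p = 0.0913).

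In all, 483 genes rose and 530 fell in Pax5ko, 308 and 325 of them by at least 2-fold. None of the 1013 called genes had overlapping groups; over all genes 34.9% did not overlap, against 10% by chance. For 42 called genes both group means lay below a signal of 64. The 483 rises became 311 without EBFko replicate 1, and 280, 315 and 297 without Pax5ko replicates 1, 2 and 3. The 530 falls became 331 and 329 without EBFko replicates 1 and 2, and 351 and 350 without Pax5ko replicates 1 and 2, and 324 (with 432 rises) when the deposited values were only centred on each array's median.

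**Figure D1:**
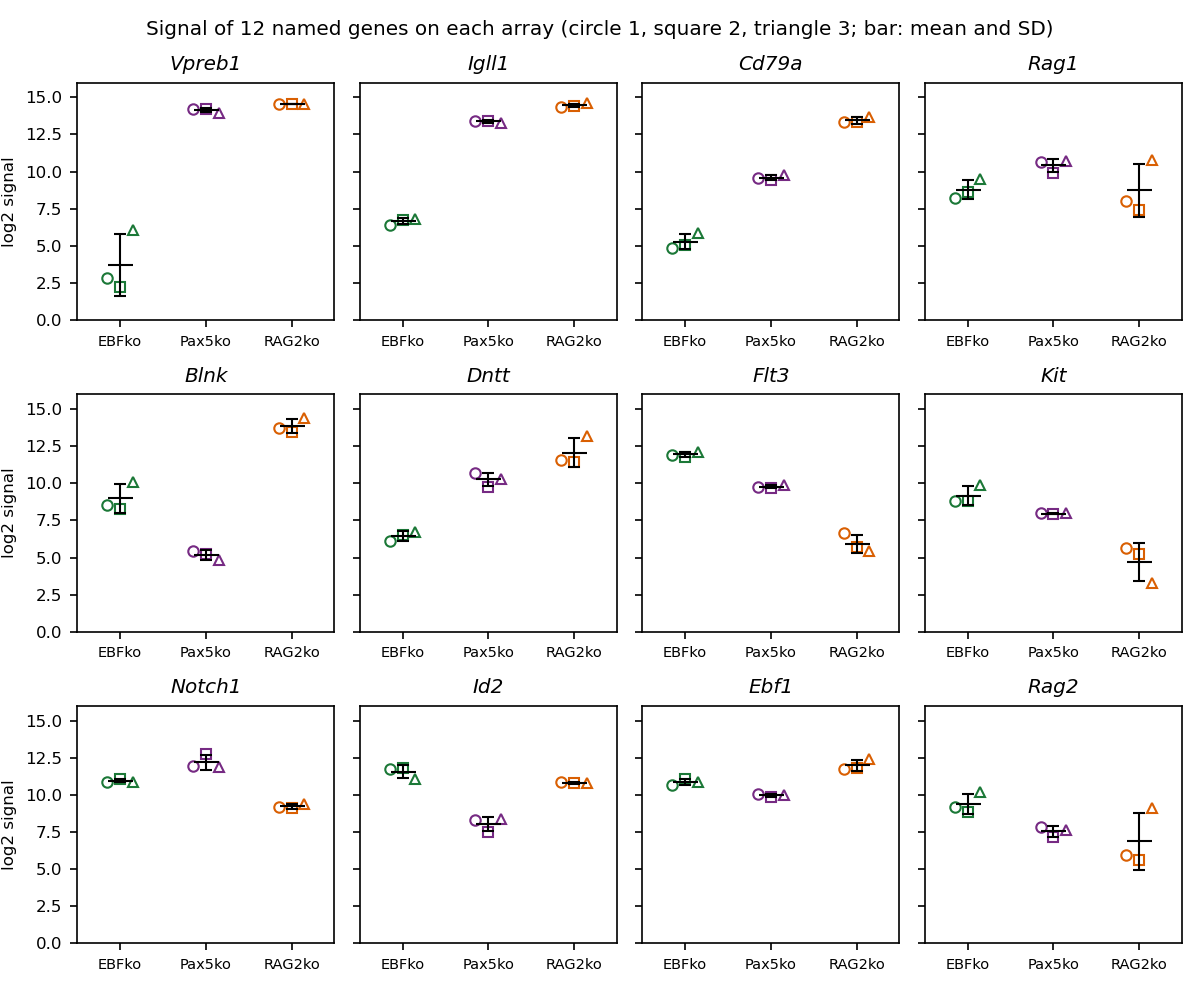
Log2 signal (vertical axis) of 12 genes on each of the 9 arrays, by knockout line (horizontal axis); circles, squares and triangles are replicates 1, 2 and 3, and bars are the mean and SD of 3 arrays. Vpreb1 and Igll1 were high in both Pax5ko and RAG2ko, Blnk was highest in RAG2ko at 13.85, and Rag2 on RAG2ko replicate 3 lay at 9.10.

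RAG2ko against Pax5ko asks what sets cells described as B lineage committed apart from those described as B lineage specified. Of 17 tested genes that Pax5 is known to activate, 10 rose and 1 fell in RAG2ko, a shift that was lost with an estimated correlation (adjusted p = 0.0907). Blnk rose by 8.68 ± 0.49 (floor 7.85), from 5.18 ± 0.31 in Pax5ko to 13.85 ± 0.47 in RAG2ko (adjusted p = 5.77e-05), Cd79a by 3.86 ± 0.26, the transcription factors Lef1 and Irf4 by 5.02 ± 0.35 and 3.04 ± 0.32, and Ebf1 by 2.03 ± 0.21 (adjusted p = 8.40e-04). Igll1 rose by 1.09 ± 0.14, a call lost when a gene's probe sets were averaged or those matching several transcripts were left out. Vpreb1 was bright in both lines and differed by 0.41 ± 0.89, which did not pass. That SE takes in the spread in EBFko (SD 2.07). The SDs were 0.14 in Pax5ko and 0.02 in RAG2ko, and the arrays of these lines did not overlap. Rag1 (-1.71), Gata3 (-2.33, floor 0.00), Tcf7 (1.06, floor 0.31), Il7r (0.27) and Csf1r (-0.70) did not pass either. Without RAG2ko replicate 3, Rag1 moved to -2.72 and passed, and its 1.67 in Pax5ko minus EBFko passed too.

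Of 17 tested genes that Pax5 is known to repress, 11 fell and 1 rose in RAG2ko. The rise was Emb (0.40 ± 0.10), whose 2 other probe sets differed the other way. Notch1 fell by 2.95 ± 0.24 (adjusted p = 3.13e-04) and Flt3 by 3.84 ± 0.29 (floor 3.55, adjusted p = 2.48e-04). Jchain, the joining chain of secreted immunoglobulin, fell by 8.21 ± 0.27, and Fcer1g, a signalling chain of Fc receptors, by 6.43 ± 0.42 (floor 3.44). Among progenitor and signalling genes, the stem cell factor receptor Kit fell by 3.25 ± 0.61 (floor 1.96), Ly6a by 4.44 ± 0.22 and the transcription factor Hhex by 5.09 ± 0.18. The chemokine receptors Ccr2 and Ccr9 fell by 7.93 ± 0.48 (floor 5.91) and 7.23 ± 0.74 (floor 5.57). Id2, in contrast, rose by 2.75 ± 0.29. Dntt rose by 1.79 ± 0.49 (adjusted p = 0.0440), a call lost without any single EBFko or Pax5ko array.

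Rises picked for their size included Enpep, the aminopeptidase known as BP-1 on pre-B cells (11.28 ± 1.20, floor 7.91), Bcat1 (7.61 ± 0.58, floor 5.92), Mc1r (7.01 ± 1.09, floor 4.21), Tubb3 (6.51 ± 0.37, floor 5.04) and Prdm8 (5.78 ± 1.11, floor 3.43). A probe set assigned to H2-Q8 rose by 6.10 ± 0.64 (floor 5.51), but its description names another MHC class I locus, so its identity is uncertain. Falls picked for their size included Tmed6 (9.23 ± 0.39, floor 5.55), Xlr4b (8.69 ± 1.08, floor 5.35), Tnni2 (8.63 ± 0.19, floor 5.65), Gcat (8.52 ± 0.32, floor 4.46), Igf2 (8.13 ± 0.67), Cybb (7.72 ± 1.28, floor 5.04) and Plagl1 (7.29 ± 1.24, floor 5.68, lost without the probe sets that match several transcripts). Ccnd2, a D-type cyclin, fell by 3.65 ± 0.18. Pfkp, a glycolytic enzyme, rose by 4.55 ± 0.22.

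Of the 24 lists, 10 shifted, and 1 of these did so with an estimated correlation as well. That 1 was the list of genes known to be repressed by Pax5, in which 1 of 17 tested members rose and 11 fell (2 and 12 adjusted over the list alone), with a median of -2.95 (adjusted p = 3.00e-08, and adjusted p = 0.0146 with an estimated correlation). The member that rose was Emb, on which probe sets disagreed. Of genes known to be activated by Pax5, 10 of 17 tested members rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 2.28 (adjusted p = 3.20e-07, and adjusted p = 0.0907 with an estimated correlation). Among B lineage transcription factors, 7 of 22 tested members rose and 0 fell (11 and 0 adjusted over the list alone) (adjusted p = 0.00156, and adjusted p = 0.397 with an estimated correlation). In the pre-B and B cell receptor list, 11 of 23 tested members rose and 4 fell (12 and 4 adjusted over the list alone) (adjusted p = 0.00498, and adjusted p = 0.512 with an estimated correlation). In the myeloid list, 1 of 25 tested members rose and 6 fell (1 and 7 adjusted over the list alone), with a median of -1.01 (adjusted p = 0.00498, and adjusted p = 0.0907 with an estimated correlation). Of stem and multipotent progenitor genes, 0 of 24 tested members rose and 8 fell (0 and 9 adjusted over the list alone) (adjusted p = 0.00519, and adjusted p = 0.0907 with an estimated correlation). The chemokine receptor and adhesion list was lower, though its shift was lost with a stricter filter (log2 above 8): 1 of 19 tested members rose and 7 fell (2 and 7 adjusted over the list alone) (adjusted p = 0.0220, and adjusted p = 0.271 with an estimated correlation).

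For 3 further lists the members moved little or the replicates disagreed. In the cell cycle list, 6 of 26 tested members rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.25 (adjusted p = 0.00498, and adjusted p = 0.565 with an estimated correlation). In the glycolysis list, 8 of 16 tested members rose and 2 fell (11 and 3 adjusted over the list alone), with a median of 0.51 (adjusted p = 0.00644, and adjusted p = 0.565 with an estimated correlation), and its shift was lost without RAG2ko replicate 3. The stromal list had a median of -2.28, yet 0 of 19 tested members rose and 0 fell (0 and 0 adjusted over the list alone) (adjusted p = 0.00247, and adjusted p = 0.565 with an estimated correlation), with RAG2ko replicate 3 near the other lines. The NK and innate lymphoid, T cell and dendritic lists did not pass (adjusted p = 0.167, 0.525 and 0.451).

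In all, 925 genes rose and 763 fell in RAG2ko against Pax5ko, 483 and 527 of them by at least 2-fold. None of the 1688 called genes had overlapping groups; over all genes 38.3% did not overlap. For 71 called genes both means lay below a signal of 64. The 925 rises became 559 and 574 without RAG2ko replicates 1 and 2. Without RAG2ko replicate 3, the only RAG2ko array with a stromal mean near that of the other lines, 1032 rose and 1090 fell.

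**Figure D2:**
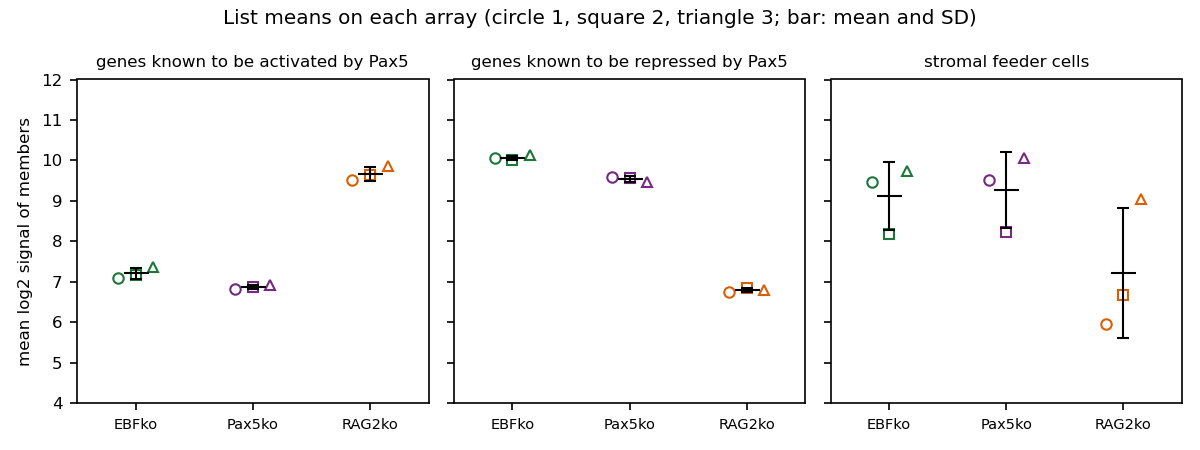
Mean log2 signal (vertical axis) of the tested members of 3 gene lists on each of the 9 arrays, by knockout line (horizontal axis); circles, squares and triangles are replicates 1, 2 and 3, and bars are the mean and SD of 3 arrays. The Pax5 lists parted RAG2ko from both other lines on every array, while the stromal list lay at 9.04 on RAG2ko replicate 3 against 5.96 and 6.68 on the other 2 RAG2ko arrays.

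RAG2ko against EBFko spans the lines at the ends of the order given in the labels. Most of the B cell genes named above were furthest apart here. Vpreb1 rose by 10.84 ± 0.89 (floor 8.51, adjusted p = 2.29e-04), Vpreb2 by 8.56 ± 0.12 (floor 8.30), Cd79a by 8.18 ± 0.26 (floor 7.45, adjusted p = 4.41e-06) and Igll1 by 7.81 ± 0.14. Pou2af1 rose by 9.70 ± 0.32 (floor 7.68), Dntt by 5.61 ± 0.49, Lef1 by 5.41 ± 0.35 (floor 5.20), Blnk by 4.88 ± 0.49 and Ebf1 by 1.14 ± 0.21. Enpep (10.14 ± 1.20, floor 7.91), Erg (8.94 ± 0.32, floor 5.20), Fgf13 (7.44 ± 0.25, floor 2.80) and Umod (7.36 ± 0.84, floor 4.30) were also picked for the size of their rise.

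Falls picked for their size included genes of progenitors and of other blood lineages. Ccr9, a homing receptor of thymic and dendritic progenitors, fell by 9.93 ± 0.74 (floor 8.27, adjusted p = 1.41e-04), Cd34 by 9.86 ± 0.67 (floor 6.63), Fcer1g by 9.51 ± 0.42 (floor 6.52), Tnni1 by 9.43 ± 0.57 (floor 6.31), P2ry14 by 9.02 ± 0.71 (floor 4.93) and Il18r1 by 8.67 ± 1.37 (floor 5.33). Gcat, B4galnt1, the T cell kinase Txk and Jchain fell by 8.36 ± 0.32 (floor 4.31), 8.19 ± 0.38 (floor 4.59), 7.79 ± 0.72 (floor 4.09) and 7.72 ± 0.27. Flt3 fell by 6.02 ± 0.29 (floor 5.73, adjusted p = 1.79e-05), Kit by 4.46 ± 0.61 (floor 3.17) and Notch1 by 1.73 ± 0.24. Gata3, a T cell transcription factor, fell by 5.02 ± 0.82 (floor 0.55, adjusted p = 0.00496), but its signals were dim, and with values below 64 raised to 64 the fall no longer passed. Id2 differed by -0.74, Il7r by 0.05, Csf1r by -0.12, Tcf7 by -0.80 and Rag1 by -0.04, and these 5 did not pass. Without RAG2ko replicate 3, Rag1 moved to -1.05 and still did not pass.

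Of the 24 lists, 11 shifted, and 5 of these did so with an estimated correlation as well. Those 5 were all lower. In the list repressed by Pax5, 1 of 17 tested members rose and 11 fell (1 and 12 adjusted over the list alone), with a median of -2.78 (adjusted p = 5.35e-08, and adjusted p = 0.0158 with an estimated correlation). The member that rose was again Emb, whose sign turned when its probe sets were averaged. Of chemokine receptor and adhesion genes, 1 of 19 tested members rose and 12 fell (1 and 14 adjusted over the list alone), with a median of -1.89 (adjusted p = 9.19e-07, and adjusted p = 0.0193 with an estimated correlation). In the stem and multipotent progenitor list, 3 of 24 tested members rose and 12 fell (4 and 13 adjusted over the list alone) (adjusted p = 6.38e-05, and adjusted p = 0.0193 with an estimated correlation), with Hoxa10 down by 7.60 ± 0.56 (floor 5.35) and Erg and Tal1 up. In the NK and innate lymphoid list, 0 of 25 tested members rose and 10 fell (0 and 12 adjusted over the list alone), with a median of -1.40 (adjusted p = 1.03e-04, and adjusted p = 0.0193 with an estimated correlation). In the myeloid list, 1 of 25 tested members rose and 8 fell (1 and 9 adjusted over the list alone) (adjusted p = 9.94e-04, and adjusted p = 0.0472 with an estimated correlation), with Fcgr3 down by 6.99 ± 0.21 (floor 6.19) and Gfi1 up by 1.11 ± 0.11.

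The other 6 lists shifted only with the preset correlation. In the pre-B and B cell receptor list, 14 of 23 tested members rose and 4 fell (14 and 6 adjusted over the list alone), with a median of 1.18 (adjusted p = 7.32e-04, and adjusted p = 0.280 with an estimated correlation). In the list activated by Pax5, 9 of 17 tested members rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 1.72 (adjusted p = 2.83e-04, and adjusted p = 0.152 with an estimated correlation). In the glycolysis list, 8 of 16 tested members rose and 1 fell (11 and 1 adjusted over the list alone) (adjusted p = 0.00159, and adjusted p = 0.326 with an estimated correlation). Its mean log2 signal was 12.56 and 12.62 on RAG2ko replicates 1 and 2, within the 12.46 to 12.67 of EBFko, and 13.19 on replicate 3, although the shift was kept without that array. Much of this gap came from Slc2a3, at 1.76 and 3.09 on replicates 1 and 2 and 9.26 on replicate 3. In EBFko it lay at 11.09 to 11.85. The list means therefore do not show that the rise of the other members rests on replicate 3. Among B lineage transcription factors, 9 of 22 tested members rose and 3 fell (9 and 4 adjusted over the list alone) (adjusted p = 0.0165, and adjusted p = 0.388 with an estimated correlation), and this shift was lost without RAG2ko replicate 3 and with array weights. In the dendritic list, 1 of 13 tested members rose and 5 fell (1 and 6 adjusted over the list alone) (adjusted p = 0.00981, and adjusted p = 0.0913 with an estimated correlation). The stromal list had a median of -2.46, and 0 of 19 tested members rose and 1 fell (0 and 1 adjusted over the list alone), the fall being Pdgfrb (adjusted p = 0.00710, and adjusted p = 0.568 with an estimated correlation).

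In all, 1070 genes rose and 1001 fell in RAG2ko against EBFko, 575 and 660 of them by at least 2-fold. None of the 2071 called genes had overlapping groups; over all genes 39.6% did not overlap. For 77 called genes both means lay below a signal of 64. The balance depended on scaling: with the deposited values centred on each array's median, 1232 rose and 723 fell, and the median difference of all genes was 0.23 in place of 0.06. Without RAG2ko replicate 3, 1256 rose and 1310 fell.

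**Figure D3:**
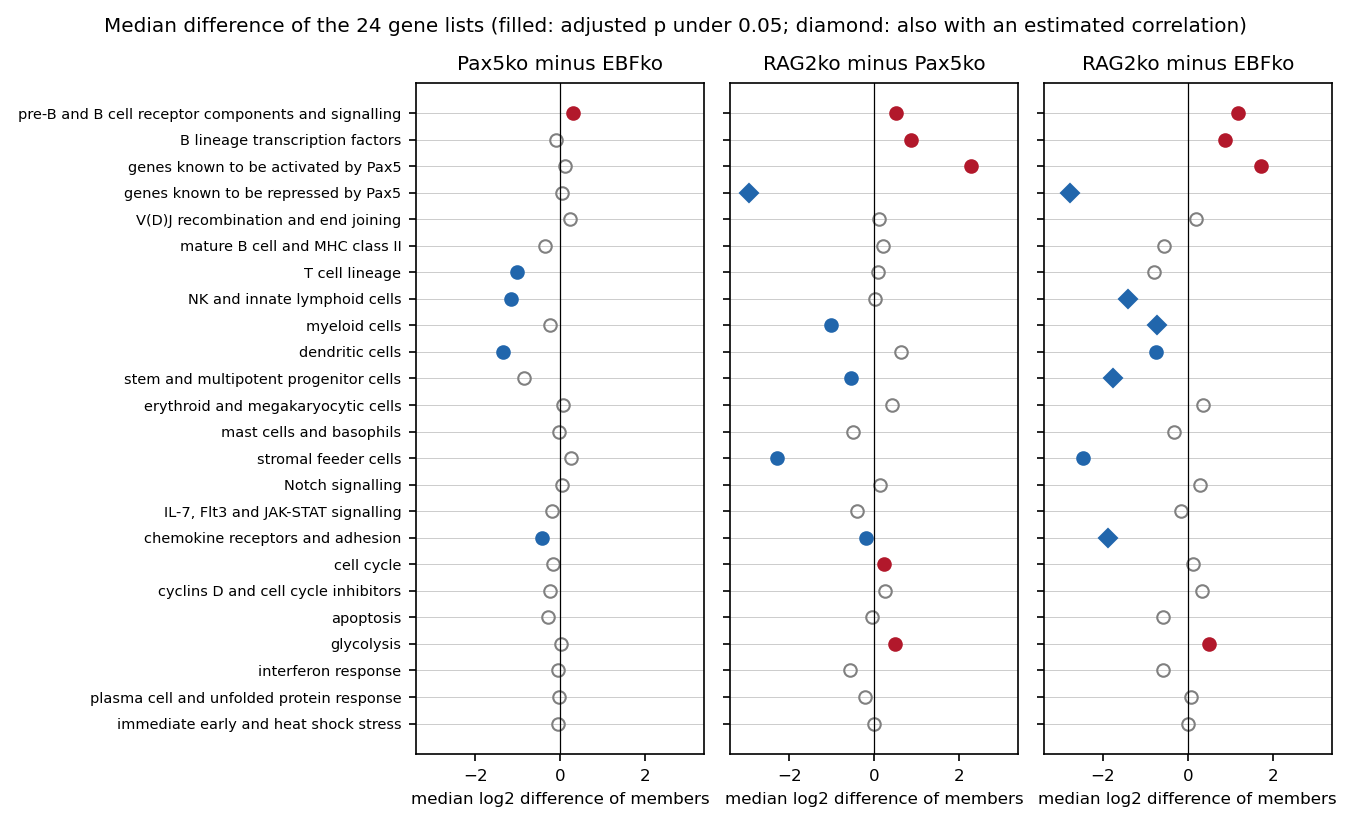
Median log2 difference (horizontal axis) of the tested members of each of the 24 gene lists (vertical axis) in the 3 comparisons. Filled symbols passed the camera test at an adjusted p under 0.05 (red higher, blue lower), diamonds also with an estimated correlation; the list repressed by Pax5 lay at -2.95 in RAG2ko minus Pax5ko and at 0.05 in Pax5ko minus EBFko.

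Another 11 lists shifted in no comparison. Their adjusted p-values are given for Pax5ko minus EBFko, RAG2ko minus Pax5ko and RAG2ko minus EBFko in turn, and their counts for RAG2ko minus EBFko. For V(D)J recombination and end joining, 4 rose and 1 fell of 16 tested (5 and 1 adjusted over the list alone), with adjusted p = 0.326, 0.671 and 0.103. For mature B cell and MHC class II genes, 2 rose and 6 fell of 18 tested (2 and 6 adjusted over the list alone), with adjusted p = 0.331, 0.870 and 0.118. Erythroid and megakaryocytic genes gave adjusted p = 0.326, 0.448 and 0.118; 2 rose and 1 fell of 15 tested (5 and 1 adjusted over the list alone), and Car2 rose by 6.43 ± 0.38. Mast cell and basophil genes gave adjusted p = 0.880, 0.592 and 0.684, and 0 rose and 0 fell of 11 tested (0 and 0 adjusted over the list alone). The Notch signalling list gave adjusted p = 0.765, 0.763 and 0.926; 3 rose and 3 fell of 15 tested (3 and 4 adjusted over the list alone), with Notch2 down by 2.44 ± 0.14 and Hes1 up by 1.03 ± 0.17. IL-7, Flt3 and JAK-STAT signalling gave adjusted p = 0.339, 0.103 and 0.0504, and 2 rose and 8 fell of 19 tested (3 and 9 adjusted over the list alone). For D cyclins and cell cycle inhibitors, 3 rose and 4 fell of 14 tested (4 and 4 adjusted over the list alone), with adjusted p = 0.432, 0.936 and 0.684. Apoptosis genes gave adjusted p = 0.145, 0.682 and 0.0889; 1 rose and 5 fell of 17 tested (2 and 6 adjusted over the list alone), and the proapoptotic Pmaip1 fell by 7.08 ± 0.70 (floor 4.55). The interferon response list gave adjusted p = 0.809, 0.0840 and 0.177, and 2 rose and 2 fell of 16 tested (2 and 2 adjusted over the list alone). In the plasma cell and unfolded protein response list, 3 rose and 2 fell of 14 tested (4 and 4 adjusted over the list alone), with adjusted p = 0.809, 0.592 and 0.926. Immediate early and heat shock genes gave adjusted p = 0.809, 0.682 and 0.704; 2 rose and 1 fell of 16 tested (2 and 2 adjusted over the list alone), and Jun rose by 3.55 ± 0.43.

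Median, mean and camera direction differed in sign for some lists, none of them shifted. In Pax5ko minus EBFko these were both Pax5 lists, B lineage transcription factors, mast cells, glycolysis, interferon response, plasma cell and immediate early genes. In RAG2ko minus Pax5ko they were mature B cell, NK, dendritic, Notch, D cyclin and immediate early genes, with the dendritic list at a median of 0.64 and a mean of -0.88. In RAG2ko minus EBFko they were Notch, D cyclin, plasma cell and immediate early genes.

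Across the 3 lines, 286 genes were higher and 296 lower in both Pax5ko and RAG2ko than in EBFko. RAG2ko stood above both other lines for 515 genes and below both for 490. Pax5ko stood above both others for 174 genes, among them Tmed6, Igf2, Crisp1 and Plagl1, and below both for 182, among them Blnk, Cd72 and Id2. A stepwise rise from EBFko through Pax5ko to RAG2ko was called for 67 genes, Cd79a and Vpreb2 included, and a stepwise fall for 61, Flt3 and Fcer1g included. If the calls of the comparisons behind each pattern were independent, 55.1, 56.6, 106, 81.5, 39.3 and 52.3 genes would fall in the first 6 patterns. Comparisons that share a line are correlated by construction: the log2 differences correlated across genes at 0.49, 0.66 and 0.33 around EBFko, RAG2ko and Pax5ko, against 0.50 around each in 100 simulations without differences, so these overlaps are not counts of independent findings. Their covariances were 0.69, 1.09 and 0.42 in the same order, against 0.19 around each in the simulations, so noise of the shared arrays alone does not account for the covariances.

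Single arrays moved several of these counts. The 286 became 187, 174 and 182 without EBFko replicate 1, Pax5ko replicate 1 and Pax5ko replicate 3, and the 296 became 189 and 196 without EBFko replicates 1 and 2. The 515 became 314 and 316 without RAG2ko replicates 1 and 2, while the 490 became 790 without RAG2ko replicate 3. The 174 became 94, 108 and 103 without Pax5ko replicates 1, 2 and 3. The 182 became 103, 103 and 120 without EBFko replicates 1, 2 and 3, 111 without Pax5ko replicate 2 and 114 without RAG2ko replicate 1.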

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

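The tests of mixed cells, of a wrong label and of stromal cells for RAG2ko replicate 3, and the test of an MHC variant, were chosen only after the result was seen; the other tests below were written down before their values were taken. The 6 arrays of a comparison can be split in 10 ways, too few for a share under 0.05. The real split gave 1013 called genes in Pax5ko minus EBFko, 1688 in RAG2ko minus Pax5ko and 2071 in RAG2ko minus EBFko, and the highest other split gave 1, 1 and 0.

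Probe sets without a single gene symbol, 24038 in number, were tested apart from the named genes. Of these, 1015, 2003 and 2600 passed in Pax5ko minus EBFko, RAG2ko minus Pax5ko and RAG2ko minus EBFko. These shares, 4.22%, 8.33% and 10.8%, were below the 10.8%, 18.0% and 22.1% of the named genes. A probe set described as inactive X specific transcripts differed by 8.38 on the log2 scale between EBFko (14.06 ± 0.15, n = 3 arrays) and Pax5ko (5.69 ± 0.20), with 7.84 ± 0.38 in RAG2ko; the Pax5ko signal was dim, so the size is uncertain.

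RAG2ko replicate 3 stood apart from RAG2ko replicates 1 and 2: the stromal list lay higher by a median of 3.46, Rag2 by 3.32 and Rag1 by 3.03. EBFko cells mixed in were argued against as the source of the whole Rag2 signal. Genes bright in EBFko and far lower on RAG2ko replicates 1 and 2 gave an upper-quartile share of 21.3% (95th percentile 95.7%), while Rag2 would need 80.3%. For Pax5ko the upper-quartile share was 27.8% (95th percentile 88.6%). Rag2 would need 373% there, out of reach whatever those genes gave, because its Pax5ko mean (7.55) lay below the 9.10 on replicate 3. The median shares were lower, 5.53% over 111 genes for EBFko and 6.21% over 105 genes for Pax5ko. They argue against an admixture as large as the upper-quartile shares, which would have shown in most of these genes. An admixture smaller than that was left open for either culture. A wrong label was argued against by a correlation of at least 0.919 with the other RAG2ko arrays, against 0.895 at most elsewhere, and poorer RNA by 3' to 5' ratios below the highest of the other 8 arrays (difference of at most -0.19). Stromal cells on every array but RAG2ko replicates 1 and 2 may account for part of it: of 378 genes lower than in Pax5ko only without replicate 3, 40.5% were also lower on replicate 2 of both other lines, against 7.58% of all other genes (Fisher's exact p = 1.82e-65, over genes that are not independent). Whether stromal cells account for Rag1 and Rag2 was not tested, and no explanation within the B lineage cells was tested.

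Of 27 MHC class I probe sets with a gene symbol, 9 were at least 2-fold higher and 2 at least 2-fold lower in RAG2ko than in Pax5ko; a further probe set without a symbol, described as D region locus 1 and not used in the test, was higher by 8.10. A strain variant under the probes may account for this, because probe sets of the same gene differed by a median range of 3.07 over 7 genes, against 0.83 in the middle of 10000 random sets and 1.68 at their 95th percentile. Grouping by symbol in place of description gave 3.07 over 5 genes. The strains are not given in the sources used here. Hybridisation across related class I genes was not tested and could give the same disagreement, so the range does not single out a strain variant. A rise of the whole class I pathway was left open by its 6 partner genes, which had a median of 0.17 with 1 higher and 1 lower.

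Igf2, Afp and Plagl1 were far higher in Pax5ko than in both other lines. Whether liver cells were carried over was left open by mixed evidence. Against it, 9 hepatocyte transcripts had a median difference of 0.17 from EBFko, with 0 called higher and 1 lower, and the named albumin gene was dim in Pax5ko (4.73). For it, a probe set described as albumin 1 and without a symbol was higher by 6.87. That probe set is marked as matching several transcripts, and whether another transcript gave its signal was not tested. For stromal cells, the lowest stromal mean of a Pax5ko array lay 1.52 below the highest of an EBFko array (-1.52). The spread between replicates made that outcome likely, and Pax5ko was slightly higher at each replicate number. Igf2 itself argued against stromal cells as its source. It was 14.62 on Pax5ko replicate 2, where the stromal mean was 8.22, and 4.12 on EBFko replicate 3, where the stromal mean was 9.75. A direct effect of the lost Pax5 on these genes was not tested.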

How the results depend on the processing

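Raising signals below 64 to 64, the filter at 8 and the test of every probe set were tests chosen only after the result was seen; the other settings were fixed before the data were examined. Of 236 named gene results that passed, 168 kept their call in every alternative fit in which the gene was tested and 68 lost it or changed sign in at least 1, most often (37) without EBFko replicate 1. The deposited ratio tables have no replicates and gave neither counts nor list tests. Medium and genotype changed together in both comparisons with RAG2ko, and the cause of the moves below was not tested.

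Array weights gave 769 genes higher in Pax5ko than EBFko (483 in the main setting) and 1345 lower in RAG2ko than Pax5ko (763). They gave 443 genes higher in both Pax5ko and RAG2ko than EBFko (286), 893 lowest in RAG2ko (490), and 276 highest and 288 lowest in Pax5ko (174 and 182). Centring the deposited values on each array's median gave 324 lower in Pax5ko than EBFko (530), 195 lower in both than EBFko (296) and 96 lowest in Pax5ko (182). Calls of at least 2-fold numbered 308 higher and 325 lower in Pax5ko than EBFko, 483 higher in RAG2ko than Pax5ko, and 575 higher and 660 lower in RAG2ko than EBFko. In the patterns they numbered 167 and 186 against EBFko, 253 highest and 326 lowest in RAG2ko and 88 lowest in Pax5ko. Testing every probe set gave 1080 higher and 1055 lower, 2040 and 2020, and 2623 and 2550 in Pax5ko minus EBFko, RAG2ko minus Pax5ko and RAG2ko minus EBFko. Signals raised to 64 gave 263 highest in Pax5ko, and the filter at 8 gave 275 lowest in Pax5ko. With an estimated correlation, 0, 1 and 5 lists shifted in place of 5, 10 and 11.

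Without 1 array at a time, 280 to 648 genes were higher and 329 to 652 lower in Pax5ko than EBFko, 559 to 1032 and 511 to 1090 in RAG2ko than Pax5ko, and 715 to 1256 and 710 to 1310 in RAG2ko than EBFko. Lists shifted numbered 5 to 6, 9 to 11 and 10 to 12. The patterns ranged over 174 to 363 higher and 189 to 366 lower against EBFko, 314 to 617 highest and 343 to 790 lowest in RAG2ko, and 94 to 229 highest and 103 to 206 lowest in Pax5ko.

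Averaged probe sets turned Emb, the 1 rise in the list repressed by Pax5, from 0.40 to -5.24 in RAG2ko minus Pax5ko. In RAG2ko minus EBFko they turned Emb to -4.95 and Xiap to -0.60. The deposited ratios turned Cd27 to 0.24 and Elane to 0.14 in RAG2ko minus Pax5ko. Replicate numbers are not known to pair samples across lines. Of 9 same-numbered pairs of arrays, 3 had deviations from their line means that correlated above 0.1, the highest at 0.16, and 6 of the 9 arrays correlated best with an array of their own number. The stromal mean was highest on replicate 3 in all 3 lines (9.75, 10.05 and 9.04). With replicate number as a block, 751, 1523 and 1873 genes were called in place of 1013, 1688 and 2071, and 23 named gene results lost their call.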

Other observations

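The gene sets and probe sets described here were tests chosen only after the result was seen. Of 9 imprinted growth genes, 3 were higher in Pax5ko than in EBFko: Igf2, Plagl1 and Grb10, the last by 4.13 on the log2 scale. Unlike Igf2 and Plagl1, Grb10 was about as high in RAG2ko (11.50) as in Pax5ko (11.35). Of 4 genes of fetal lymphoid cells, 3 were lower in RAG2ko than in Pax5ko: Igf2bp3 by 5.38, Hmga2 by 1.59 and Arid3a by 1.14. None of those 4 passed between Pax5ko and EBFko.

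Among probe sets without a gene symbol, several described as T cell receptor transcripts differed between the lines. A T cell receptor beta variable 13 probe set rose by 6.88 in Pax5ko against EBFko and fell by 7.86 in RAG2ko against Pax5ko. A T cell receptor gamma probe set fell by 10.59 in Pax5ko and 8.20 in RAG2ko against EBFko. A rearranged T cell receptor delta probe set fell by 9.24 in RAG2ko against Pax5ko and 9.66 against EBFko. How far these sizes rest on dim signal was not tested.

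The 3 Y-linked genes tested were lower in RAG2ko than in Pax5ko. Eif2s3y, for example, had a mean log2 signal of 6.56 in EBFko, 10.99 in Pax5ko and 3.05 in RAG2ko. Kdm5d was also higher in Pax5ko than in EBFko, by 4.39 (adjusted p = 0.0168), while Eif2s3y and Uty did not pass there. The size for Kdm5d rests on dim signal in EBFko (4.91), and its floor is not given here. Xist probe sets, described as inactive X specific transcripts, differed the other way between these 2 lines. Their means were 12.94, 8.81 and 14.06 in EBFko against 2.21, 3.85 and 5.69 in Pax5ko. In RAG2ko they were 5.81, 4.50 and 7.84, also below EBFko, so RAG2ko was low in Y-linked and in Xist signal alike. Sex-linked transcripts thus differed together with the genotype here too, and the design cannot tell the 2 apart. Several of these signals were dim.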
